A study of Drosophila melanogaster with 11 samples.

How the data were processed

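Adult female heads of the w1118 strain were pooled in groups of 20 per array. Flies received 0 or 0.1 mg/ml nicotine in their food for 10 days, then 0 or 5 mM paraquat, a herbicide that generates superoxide, for a further 6 days on the same nicotine dose. Total RNA was extracted with Tri Reagent, cleaned on RNeasy columns, amplified from the 3' end with a NuGEN kit, labelled with biotin and hybridised to Affymetrix Drosophila arrays. The submitters left out 1 degraded paraquat replicate before normalization, so paraquat without nicotine had 2 arrays and each other group 3. That replicate was not analysed here.

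The deposited values are log2 expression values per probe set. The submitters' processing notes name GCRMA, which adjusts background, normalizes quantiles between arrays and summarizes probes. The version of GCRMA and its settings are not given in the sources used here. The table held 18952 probe sets on 11 arrays, with values from 2.11 to 16.2, and 39.9% of values lay within 0.01 of the minimum. No value was rescaled or transformed further, and 0 pairs of arrays were identical.

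From there, 183 Affymetrix control probe sets and probe sets reaching log2 4 on fewer than 2 arrays were left out, and 9104 probe sets were tested. Of these, 7800 named 1 gene, 228 named several genes and 1076 named none. Symbols come from the platform annotation, brought up to date through its gene identifiers with the RefSeq gene table of Drosophila Release 6 for 7776 probe sets, while 24 kept the annotation's symbol. The sources name no genome build for the arrays, so no coordinates are given.

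A limma model with 1 mean per group was fitted to the 11 arrays with no block, and moderated statistics (lmFit, eBayes with its default prior, 7 residual and 2.48 prior degrees of freedom) gave 8 contrasts. These were paraquat without nicotine, paraquat with nicotine, both paraquat contrasts averaged, nicotine without paraquat, nicotine with paraquat, both nicotine contrasts averaged, the joint exposure against control, and the interaction. Benjamini-Hochberg adjustment ran over the 9104 probe sets within each contrast, and a probe set was called at an adjusted p below 0.05. All tests were two-sided. Errors after ± are standard errors from the model unless SD is written, and n is the number of arrays per group. Where a compared group had all arrays below log2 4, every value below log2 4 in the lower groups was set to log2 4 for the fold, which is then written as "at least", and no fold is given where both groups lay there.

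The design, the tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. The rule names, for the paraquat and nicotine contrasts, the 12 largest rises and 12 largest falls among called probe sets of exactly 1 gene with no overlap between the groups. It names 6 and 6 for the joint contrast, nicotine averaged and the interaction, and the 5 smallest p-values where fewer than 5 passed. Up to 4 members of each list with the smallest p are named too. It also names the study's subject genes ple, Ddc, Sod1, Sod2, Cat, GstD1, Hsp22, Hsp70Aa, park and Pink1. Sod1 and park had no tested probe set of their own, and Hsp22 and Hsp70Aa had only probe sets shared between genes, so these were not analysed here.

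The 33 gene lists were tested with camera (limma, preset correlation 0.01) on 1 probe set for each of 7316 genes, with adjustment over the lists within a contrast. They cover detoxification (glutathione S-transferases, cytochrome P450s, UDP-glycosyltransferases), antioxidant and glutathione enzymes, heat shock proteins, endoplasmic reticulum stress, antimicrobial peptides, immune recognition and signalling, Turandot and JAK-STAT genes, and apoptosis, DNA damage and JNK genes. Nervous system lists were phototransduction, monoamine pathway, Parkinson's disease orthologues, cholinergic, neuronal, glial, circadian clock, neuropeptides and odorant-binding proteins. Tissue lists were head fat body, haemocyte, muscle, digestive tract, ovary and cuticle. Metabolic and other lists were oxidative phosphorylation, cytosolic ribosome, proteasome, insulin and starvation, lipid and glycogen metabolism, glycolysis, metal handling and autophagy. In the cholinergic, ovary and odorant-binding lists 1 member each matched no gene. With the correlation estimated from the data in place of the preset value, 0 of the list calls held in any contrast. A second list of midgut genes was written after the digestive tract values were seen and was used only to examine them.

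Alternatives set beforehand were no low-value filter, a filter at log2 6, a variance trend with a robust prior, only the arrays of the groups compared, centring of each array on its median, array weights, the replicate number as a block, a covariate for the 3' minus 5' difference of control probe sets, 1 probe set per gene, and leaving out each array in turn. For lists they were estimated correlation, ranks, no filter, the block, the covariate and leaving out each array. Added after seeing the data were a covariate for the 3' minus middle difference, a fit without control replicate 3 and paraquat with nicotine replicate 1, and a fit without paraquat with nicotine replicates 1 and 2.

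In a self-test on simulated values for 9104 probe sets, the averaged paraquat contrast recovered 22.4% of 1.5-fold, 55.2% of 2-fold and 81.8% of 4-fold changes, with 5 false calls. Paraquat against control recovered 2.99%, 22.4% and 68.2% with 2 false calls, and nicotine against control 1.49%, 29.9% and 75.8% with 2. Nicotine averaged recovered 23.9%, 59.7% and 89.4% with 10 false calls. The interaction recovered 0% of 1.5-fold and 2-fold changes and 48.5% of 4-fold changes, with 1. A simulated list of 20 genes shifted by 0.5 log2 was called by camera in 8 of 8 contrasts with 0 unshifted lists called, and with the estimated correlation it was missed for the interaction (adjusted p = 0.300). Simulated genes varied independently of each other, so the self-test says nothing on false list calls among correlated genes. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.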

Results

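Gene expression was measured in heads of female flies kept for 16 days on plain food (control, n = 3 arrays), on food with paraquat for the last 6 days (n = 2), on food with nicotine throughout (n = 3), or on both (the joint exposure, n = 3). Between 8729 and 9001 probe sets lay above log2 4 on each array, and array medians lay between 2.88 and 3.30. The mean correlation of an array with the others across probe sets ran from 0.914 for joint exposure replicate 1 to 0.965. The number of arrays limits the precision. Nothing in the sources says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these pooled samples.

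The first question was which transcripts of the head paraquat changed, averaged over flies without and with nicotine. Genes past the test included Cyp6d2 and DNA end-binding genes among the rises, and Gpdh1 and ornithine decarboxylase genes among the falls. The cytochrome P450 gene Cyp6d2 rose by 4.77 ± 0.34 log2 (27.4-fold, adjusted p = 0.000276). Its group means were 8.53 ± 0.61 (SD, n = 3) in control and 13.35 ± 0.41 (n = 2) with paraquat, and 8.34 ± 0.63 (n = 3) with nicotine and 13.07 ± 0.71 (n = 3) with both. Ku80, whose product binds broken DNA ends, rose by 3.91 ± 0.41 log2 (adjusted p = 0.00164). Its partner Irbp rose by 2.25 ± 0.32 (adjusted p = 0.00710). Gpdh1, which encodes glycerol-3-phosphate dehydrogenase, fell by 2.06 ± 0.25 log2 (4.17-fold, adjusted p = 0.00349). It went from 11.95 ± 0.42 (SD, n = 3) in control to 9.18 ± 0.33 (n = 2) with paraquat and from 11.39 ± 0.22 to 10.04 ± 0.66 (n = 3 each) on nicotine. The ornithine decarboxylase genes Odc2 and Odc1 fell by 2.41 ± 0.29 (adjusted p = 0.00326) and 2.33 ± 0.38 log2 (adjusted p = 0.0112).

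**Figure D1:**
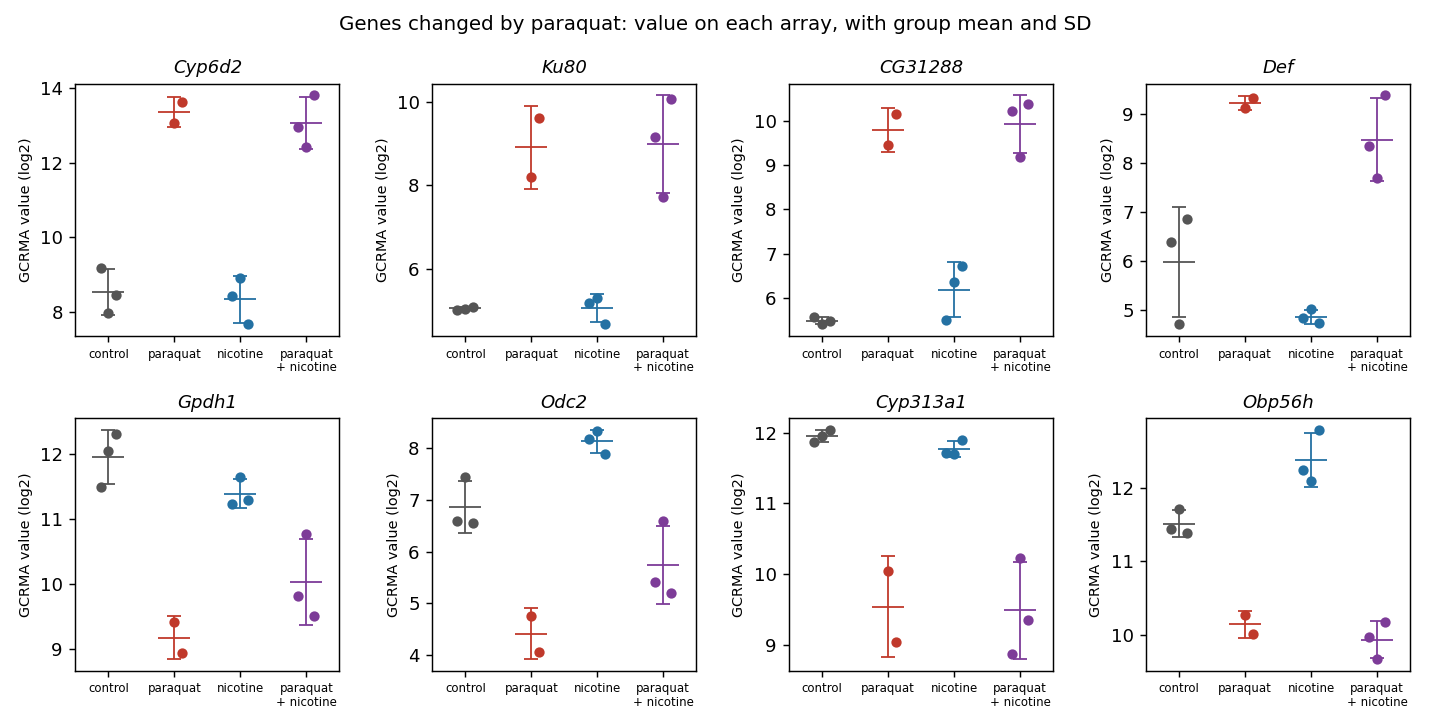
Expression (GCRMA log2) of Cyp6d2, Ku80, CG31288, Def, Gpdh1, Odc2, Cyp313a1 and Obp56h on each array (points) with group mean and SD, for control, paraquat, nicotine and both. Cyp6d2 means were 8.53 and 8.34 without paraquat and 13.35 and 13.07 with it.

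Other large rises included a germline Piwi protein gene, a nucleotide synthesis gene, a lipid synthesis gene and many genes known by number only. The gene aub of the piRNA pathway rose by 5.01 ± 0.80 log2 (32.2-fold, adjusted p = 0.0112) and the ribonucleotide reductase gene RnrL by 4.11 ± 0.53 (17.2-fold, adjusted p = 0.00427). CG12766 rose by 4.08 ± 0.45 (16.9-fold, adjusted p = 0.00195). CG31288 (4.03 ± 0.29, adjusted p = 0.000276) and CG16898 (3.75 ± 0.28, adjusted p = 0.000302), which encode kinase-like proteins, rose 16.4-fold and 13.4-fold. CG12224 rose 12.5-fold (3.64 ± 0.35, adjusted p = 0.00129). Against groups that lay below log2 4, CG33468 was at least 24.97-fold higher (adjusted p = 0.00351), and CG30289 at least 8.03-fold (adjusted p = 0.0112). In the same way the diacylglycerol acyltransferase gene Dgat2 was higher at least 7.42-fold (adjusted p = 0.00261) and Ote, which encodes a nuclear lamina protein, at least 4.99-fold (adjusted p = 0.00285). Among the falls, CG7763 was at least 9.37-fold lower (adjusted p = 0.0112) and CG7214 at least 4.30-fold lower (adjusted p = 0.0136). Diedel (-3.04 ± 0.56 log2), the odorant-binding gene Obp99a (-2.69 ± 0.59), CG8654 (-2.45 ± 0.45), nompA (-2.44 ± 0.35) and Cyp313a1 (-2.35 ± 0.26) fell too. So did the sugar-responsive transcription factor gene sug (-2.12 ± 0.30) and the phosphatidylserine decarboxylase gene Pisd (-1.94 ± 0.42). Adjusted p ran from 0.00195 for Cyp313a1 to 0.0374 for Obp99a.

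In all, 336 of 9104 probe sets were called, 267 higher and 69 lower, naming 292 genes, and 235 of them changed at least 2-fold (180 higher, 55 lower). The median change was 1.30 log2 among the higher and -1.35 among the lower. The count depended on single arrays. It was 53 without paraquat replicate 3, and those 53 were all among the 336. It was 167 without nicotine replicate 1, 190 without control replicate 2 and 191 without paraquat replicate 2. It was 213 without nicotine replicate 3, 222 without nicotine replicate 2 and 586 without joint exposure replicate 2. Of the 24 genes named by size, such as Cyp6d2, Ku80 and Gpdh1, 13 kept their call without paraquat replicate 3 and 20 without paraquat replicate 2 or nicotine replicate 1. The number was 21 without control replicate 2 or nicotine replicate 3, and 22 without control replicate 1, control replicate 3, nicotine replicate 2 or joint exposure replicate 3.

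Cytochrome P450 genes called with paraquat included Cyp309a1 (3.01 ± 0.32, adjusted p = 0.00164) and Cyp12c1 (2.05 ± 0.26, adjusted p = 0.00418) beside Cyp6d2 and the lower Cyp313a1. Of 58 measured P450 genes 8 were called higher and 2 lower, 13 and 8 when adjusted over the list alone. The list's median was -0.01 while its test pointed up (camera adjusted p = 0.897). Among glutathione S-transferases GstD3 rose by 2.30 ± 0.23 log2 (adjusted p = 0.00129) and GstE7 by 2.11 ± 0.23 (adjusted p = 0.00195). GstD4 was at least 1.37-fold higher (adjusted p = 0.0223), while GstZ2 was at -1.90 (adjusted p = 0.0546). Of 30 members 3 were called higher and 0 lower, 8 and 1 when adjusted over the list alone. The list median was 0.20 (camera adjusted p = 0.0168, and adjusted p = 0.568 with an estimated correlation). That list call was lost without control replicate 1 (adjusted p = 0.0647), joint exposure replicate 2 (0.0743) or nicotine replicate 2 (0.0592). It was also lost with the replicate number as a block. Ugt49C1 (1.71 ± 0.17, adjusted p = 0.00129), Ugt301D1 (1.55 ± 0.27, adjusted p = 0.0147) and Ugt302C1 (1.17 ± 0.25, adjusted p = 0.0348) rose. Of 16 UDP-glycosyltransferase genes 3 were called higher and 5 when adjusted over the list alone (median 0.03, camera adjusted p = 0.196).

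The measured classical antioxidant, chaperone and dopamine genes were not called, while Sod1, Hsp22 and Hsp70Aa were not analysed. Cat was at 0.28 ± 0.14 log2 (adjusted p = 0.340), Sod2 at -0.23 ± 0.18 (0.568), and GstD1 at 0.67 ± 0.17 (0.0711). The dopamine pathway's tyrosine hydroxylase gene ple was at -0.30 ± 0.16 (0.363), Ddc at -0.17 ± 0.15 (0.622) and Pink1 at -0.28 ± 0.17 (0.452). Of 21 antioxidant and glutathione genes 0 were called by limma and 1, higher, when adjusted over the list alone. Trxr1 was at 0.66 (adjusted p = 0.0514) and the list median at 0.08 (camera adjusted p = 0.430). Heat shock proteins had a median of 0.13 over 9 genes (camera adjusted p = 0.363), with Stip1 at 0.45 (adjusted p = 0.148) and Hsp60A at 0.44 (0.389). The 18 endoplasmic reticulum stress genes had one of -0.07 (camera adjusted p = 0.593), with Ero1L at 0.56 (0.116). Among 9 Parkinson's disease orthologues iPLA2-VIA rose by 0.62 ± 0.12 log2 (adjusted p = 0.0232), the 1 call over all probe sets and adjusted over the list alone. That list had a median of 0.06 (camera adjusted p = 0.546). The autophagy list had a median of 0.06 over 21 genes (camera adjusted p = 0.546), with ref(2)P higher by 0.66 ± 0.13 (adjusted p = 0.0239). Centring each array on its median shifted this contrast by -0.07 log2 and the paraquat contrast without nicotine by -0.11. With it the small medians of the autophagy, Parkinson's disease and UDP-glycosyltransferase lists turned negative, and no called list changed sign.

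Proteasome and metal-handling genes were mostly higher. The median over 26 proteasome genes was 0.39 log2, 25 of them higher (camera adjusted p = 3.97e-06, and adjusted p = 0.551 with an estimated correlation). Prosalpha6 (0.83 ± 0.15, adjusted p = 0.0170), Prosbeta4 (0.78 ± 0.17, adjusted p = 0.0384) and Rpn2 (0.51 ± 0.11, adjusted p = 0.0400) were called, and 6 were when adjusted over the list alone. All 13 metal-handling genes were higher, with a median of 0.41 (camera adjusted p = 6.34e-05, and adjusted p = 0.252 with an estimated correlation). The metallothionein gene MtnD rose by 3.02 ± 0.49 log2 (adjusted p = 0.0112) and Irp-1B by 1.26 ± 0.21 (adjusted p = 0.0127). The ferritin genes Fer1HCH and Fer2LCH rose by 0.56 ± 0.10 (adjusted p = 0.0170) and 0.56 ± 0.11 (adjusted p = 0.0267). These 4 metal-handling genes were called, and 5 were when adjusted over the list alone. In the apoptosis, DNA damage and JNK list 11 of 15 genes were higher, with 3 called and 5 when adjusted over the list alone. Its median was 0.29 (camera adjusted p = 0.00434, and adjusted p = 0.551 with an estimated correlation). These 3 lists kept their calls whichever array was left out, and the last lost its call without control replicate 3 and joint exposure replicate 1 together (adjusted p = 0.0636).

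Neuropeptide transcripts were lower throughout. All 22 measured neuropeptide genes were lower with paraquat, with a median of -0.42 log2 (camera adjusted p = 1.39e-08, and adjusted p = 0.252 with an estimated correlation). Nplp3 fell by 0.84 ± 0.18 log2 (adjusted p = 0.0372). Lk was at -0.78 (adjusted p = 0.0755), Nplp1 at -0.59 (0.110) and Dh31 at -0.43 (0.123). Nplp3 was the 1 neuropeptide gene called lower, and 2 were when adjusted over the list alone. The neuronal list had 16 of 18 genes lower (median -0.32, camera adjusted p = 0.000327, and adjusted p = 0.409 with an estimated correlation). In it futsch was at -0.85 (0.189), brp at -0.62 (0.260) and elav at -0.35 (0.255). Medians were -0.23 for 15 monoamine pathway genes (camera adjusted p = 0.00857), including Vmat at -0.33 (0.302), and -0.21 for 12 cholinergic genes (camera adjusted p = 0.00971), including VAChT at -0.26 (0.296). Both had adjusted p = 0.409 with an estimated correlation. Phototransduction genes had a median of -0.16 over 20 genes (camera adjusted p = 0.00529, and adjusted p = 0.551 with an estimated correlation), with rdgA at -0.98 (0.0809). For the neuronal, monoamine, cholinergic and phototransduction lists 0 members were called by limma, and 0 when adjusted over the list alone. Glial genes had a median of -0.17 over 14 genes (camera adjusted p = 0.168) and circadian clock genes -0.01 over 10 (camera adjusted p = 0.345), with Clk at -0.88 (0.122).

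Odorant-binding proteins went both ways. Obp56h fell by 1.90 ± 0.17 log2 (adjusted p = 0.000871) and Obp57b by 0.57 ± 0.13 (adjusted p = 0.0439), and Obp99b rose by 1.47 ± 0.16 (adjusted p = 0.00195). Of 30 genes 1 was called higher and 3 lower, 1 and 5 when adjusted over the list alone (median -0.21, camera adjusted p = 0.00687, and adjusted p = 0.551 with an estimated correlation). In the immune lists the peptide gene Def rose by 3.43 ± 0.41 log2 (adjusted p = 0.00297) while Drsl4 fell by 3.72 ± 0.84 (adjusted p = 0.0435), 2 of 15 antimicrobial peptide genes called against 2 higher and 2 lower when adjusted over the list alone. That list had a median of -0.08 (camera adjusted p = 0.261). PGRP-LB (0.80 ± 0.16, adjusted p = 0.0268) and Myd88 (0.74 ± 0.16, adjusted p = 0.0328) rose and PGRP-SB1 fell by 1.89 ± 0.44 (adjusted p = 0.0499). These were the calls among 21 recognition and signalling genes, and 4 were higher and 1 lower when adjusted over the list alone (median 0.14, camera adjusted p = 0.358). TotC fell by 1.92 ± 0.40 log2 (adjusted p = 0.0299), the 1 call among 4 Turandot and JAK-STAT genes, also adjusted over the list alone (median -0.12, camera adjusted p = 0.230).

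Fat and glycogen genes were mostly lower. In the lipid and glycogen list 14 of 17 genes were lower (median -0.39, camera adjusted p = 0.000165, and adjusted p = 0.551 with an estimated correlation). FASN2 fell by 1.05 ± 0.24 log2 (adjusted p = 0.0499), with whd at -1.19 (0.0559) and Treh at -0.74 (0.0592). Dgat2 was called higher and FASN2 lower, and 1 and 10 genes were when adjusted over the list alone. Head fat body genes had a median of -0.47 over 9 genes (camera adjusted p = 0.00529, and adjusted p = 0.551 with an estimated correlation). Of these 0 were called by limma, and 1 higher and 6 lower when adjusted over the list alone, with Lsp2 at -1.36 (adjusted p = 0.0719) and Yp3 at -0.88 (0.140). In the insulin and starvation list ImpL2 rose by 1.02 ± 0.18 log2 (adjusted p = 0.0141) and foxo fell by 0.65 ± 0.14 (adjusted p = 0.0396) beside sug. Of 14 members 2 were higher and 5 lower when adjusted over the list alone (median -0.18, camera adjusted p = 0.0813). Glycolysis genes had a median of -0.13 over 10 genes (camera adjusted p = 0.230).

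Smaller shifts concerned translation and respiration. The median was -0.15 log2 over 35 cytosolic ribosome genes (camera adjusted p = 0.00244, and adjusted p = 0.568 with an estimated correlation). It was -0.14 over 59 oxidative phosphorylation genes (camera adjusted p = 0.00604, and adjusted p = 0.668 with an estimated correlation). RpL3 was at -0.26 (0.210) and ND-B12 at 0.67 (0.0615), with 0 members of either called by limma or adjusted over the list alone. The respiration call was lost without control replicate 3 (adjusted p = 0.0952), joint exposure replicate 1 (0.0783) or nicotine replicate 3 (0.0948). With a covariate for the 3' minus middle difference of the control probe sets, the calls of the ribosome (adjusted p = 0.0718), respiration (0.343), odorant-binding (0.0746), head fat body (0.0535) and digestive tract (0.186) lists were lost. Lcp65Ac was at least 2.26-fold lower (adjusted p = 0.0252) among 21 cuticle genes (median -0.11, 1 called and 1 adjusted over the list alone, camera adjusted p = 0.0647). Medians of the other tissue lists were 0.10 for 15 haemocyte genes, where Nplp2 fell by 1.003 ± 0.21 log2 (adjusted p = 0.0348, camera adjusted p = 0.931). They were -0.06 for 16 muscle genes (camera adjusted p = 0.363) and 0.07 for 7 ovary genes (camera adjusted p = 0.745), the last including aub.

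**Figure D2:**
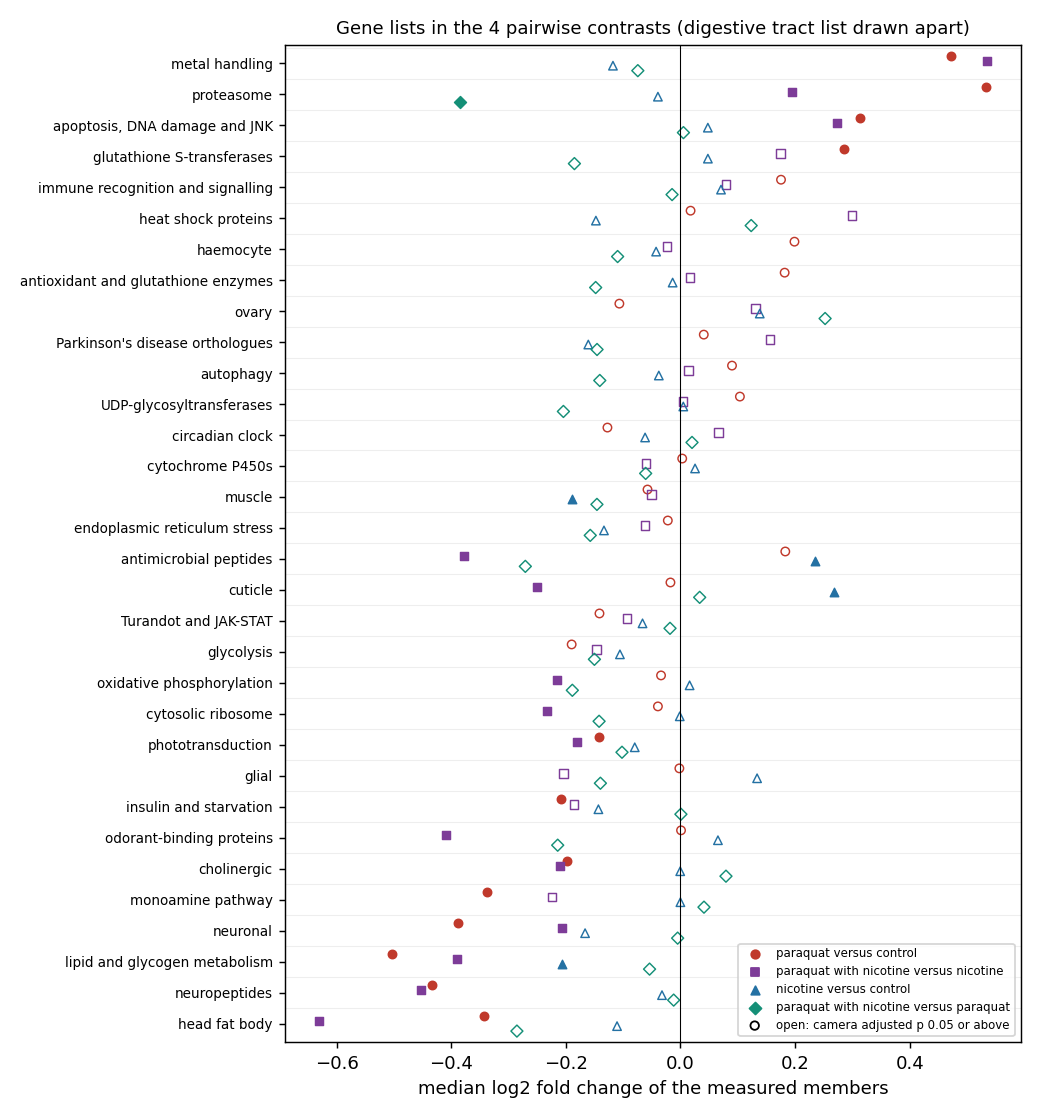
Median log2 fold change of the measured members of 32 gene lists in the 4 pairwise contrasts, filled where the camera adjusted p lay below 0.05 with the preset correlation and open otherwise. The proteasome list lies at 0.53 without nicotine and 0.19 with it, and the neuropeptide list at -0.43 and -0.45.

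Without nicotine, the question was what paraquat changed in flies on otherwise plain food. Cyp6d2 rose by 4.82 ± 0.51 log2 (28.3-fold, adjusted p = 0.00858, n = 3 and 2), and the aldehyde oxidase gene AOX1 by 3.29 ± 0.30 (9.77-fold, adjusted p = 0.00550). The kinase-like genes CG31288 (4.32 ± 0.43, adjusted p = 0.00705) and CG13659 (4.13 ± 0.48, adjusted p = 0.0162) rose too. So did CG16898 (3.44 ± 0.41, adjusted p = 0.0166) and CG11893 (3.21 ± 0.45, adjusted p = 0.0304). Gpdh1 fell by 2.77 ± 0.38 log2 (6.83-fold, adjusted p = 0.0304) and Cyp313a1 by 2.41 ± 0.39 (5.33-fold, adjusted p = 0.0465). Further rises were Dgat2 (with no size, because its control mean lay below log2 4), Ku80 (14.7-fold), CG12224 (10.4-fold) and CG15347 (8.85-fold). CG33468 was at least 33.4-fold and Ote at least 6.23-fold higher, and adjusted p for these 6 genes lay between 0.0166 and 0.0494. CG13833 fell as well (adjusted p = 0.0314), with values too low for a fold. The subject genes were not called. Values were -0.34 for ple (adjusted p = 0.710) and -0.18 for Ddc (0.886), with Sod2 at -0.07 (0.982), Cat at 0.45 (0.475), GstD1 at 0.62 (0.425) and Pink1 at -0.17 (0.915).

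Here 31 probe sets were called, 27 higher and 4 lower, and 960 had an unadjusted p below 0.05, where chance would give 455. The paraquat group had 2 arrays, and the calls depended on single ones. The count was 0 without paraquat replicate 3, 1 without paraquat replicate 2, 2 without control replicate 3 and 5 without control replicate 2. It was 9 without nicotine replicate 1, 11 without control replicate 1, 94 without joint exposure replicate 3 and 103 without joint exposure replicate 2. Cyp6d2, AOX1 and the other genes named here numbered 15. Of these 0 kept their call without paraquat replicate 3, 1 without paraquat replicate 2 or control replicate 3 and 4 without control replicate 2. The number was 6 without control replicate 1 or nicotine replicate 1, 9 without nicotine replicate 2, 10 without nicotine replicate 3 and 11 without joint exposure replicate 1. With the replicate number as a block 9 probe sets were called, and 5 of the 15 genes kept their call. With no filter, or without control replicate 3 and joint exposure replicate 1 together, 1 of the 15 did. With only the groups compared 3 did, and with the 3' minus 5' covariate 7.

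By list, all 26 proteasome genes were higher without nicotine (median 0.53, camera adjusted p = 4.01e-08, and adjusted p = 0.512 with an estimated correlation). Neuropeptides had 21 of 22 genes lower (median -0.43, adjusted p = 4.01e-08). Medians were -0.50 for lipid and glycogen (1.56e-05), -0.39 for neuronal (4.50e-05), -0.34 for monoamine (0.00543) and -0.21 for insulin and starvation genes (0.0196). They were -0.20 for cholinergic genes (0.0160) and 0.47 for metal handling (0.00431). Each of these 7 had adjusted p = 0.379 with an estimated correlation. Glutathione S-transferases (0.29, adjusted p = 0.00543) and phototransduction genes (-0.14, adjusted p = 0.00543) had adjusted p = 0.518 with an estimated correlation. Apoptosis, DNA damage and JNK genes (0.31, adjusted p = 0.00537) had adjusted p = 0.512 with an estimated correlation, and head fat body genes (-0.34, adjusted p = 0.00819) adjusted p = 0.537 with an estimated correlation. Of 12 list calls 10 held without control replicate 1 or paraquat replicate 3 and 11 without control replicate 3 or paraquat replicate 2. The glutathione S-transferase call was lost without control replicate 1 (adjusted p = 0.0703), and the monoamine call without paraquat replicate 3 (0.0557). The glutathione S-transferase and cholinergic calls were lost with the replicate number as a block (0.0535 and 0.0789). The cholinergic call was also lost without either of these arrays (0.0941 and 0.137), and the insulin call without control replicate 3 (0.0647) or paraquat replicate 2 (0.0832) and in the test by ranks (0.0845). Without control replicate 3 and joint exposure replicate 1 together the apoptosis and insulin calls were lost (0.0649 each), and with the 3' minus 5' covariate the head fat body call was (0.0514).

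On nicotine, the question was what paraquat changed in flies already exposed to nicotine. Cyp6d2 rose by 4.73 ± 0.45 log2 (26.5-fold, adjusted p = 0.00308, n = 3 and 3), and CG16898 by 4.06 ± 0.37 (16.6-fold, adjusted p = 0.00247). Ku80 rose by 3.95 ± 0.55 (15.4-fold, adjusted p = 0.0163) and AOX1 by 3.39 ± 0.27 (10.5-fold, adjusted p = 0.00127). The defensin gene Def rose by 3.62 ± 0.55 (12.3-fold, adjusted p = 0.0257) and GstE9 by 3.44 ± 0.55 (10.8-fold, adjusted p = 0.0332). Obp56h fell by 2.44 ± 0.22 log2 (5.42-fold, adjusted p = 0.00247), from 12.37 ± 0.37 to 9.94 ± 0.25 (SD, n = 3 each), and Hpd, of tyrosine breakdown, by 1.55 ± 0.26 (2.93-fold, adjusted p = 0.0396). Further rises were CG12766 (19.1-fold), CG12224 (14.9-fold), CG31288 (13.4-fold), Dgat2 (at least 4.48-fold), Ote (at least 3.997-fold) and CG31296 (at least 2.87-fold, adjusted p = 0.000477). Further falls were Odc2 (5.22-fold, adjusted p = 0.0381), Cyp313a1 (4.85-fold, adjusted p = 0.0257) and CG13833 (adjusted p = 0.0108, too low for a fold). Not called were ple at -0.27 (adjusted p = 0.693), Ddc at -0.16 (0.835), Sod2 at -0.39 (0.594), Cat at 0.10 (0.900), GstD1 at 0.72 (0.261) and Pink1 at -0.38 (0.582).

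On nicotine 41 probe sets were called, 36 higher and 5 lower, and 1050 had an unadjusted p below 0.05. The count was 12 without nicotine replicate 1, 16 without nicotine replicate 3, 25 without paraquat replicate 2 or 3 and 26 without control replicate 2. It was 63 without joint exposure replicate 3 and 242 without joint exposure replicate 2. Of the 17 genes named by size, among them Cyp6d2 and Obp56h, 8 kept their call without nicotine replicate 1 or joint exposure replicate 1 and 9 without nicotine replicate 3. The number was 11 without nicotine replicate 2, paraquat replicate 2 or 3 or joint exposure replicate 3, 12 without control replicate 2, 13 without control replicate 1 and 15 without control replicate 3. With the 3' minus middle covariate 8 of the 17 kept their call, with no filter 5, and with only the groups compared 2.

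Metal-handling genes were higher on nicotine too, 13 of 13 (median 0.54, camera adjusted p = 9.66e-06, and adjusted p = 0.348 with an estimated correlation). Neuropeptides were lower, 22 of 22 (median -0.45, camera adjusted p = 6.56e-06, and adjusted p = 0.541 with an estimated correlation). Odorant-binding genes had a median of -0.41 (camera adjusted p = 0.000113) and digestive tract genes one of 4.11 (camera adjusted p = 3.85e-06), both with adjusted p = 0.595 with an estimated correlation. Medians were -0.23 for cytosolic ribosome (0.000162), -0.21 for oxidative phosphorylation (0.000608), 0.19 for proteasome (0.00664), and 0.27 for apoptosis, DNA damage and JNK genes (0.00667). Lipid and glycogen genes lay at -0.39 (0.0141), antimicrobial peptides at -0.38 (0.0171) and head fat body genes at -0.63 (0.0171). Neuronal genes lay at -0.21 (0.0263), cuticle at -0.25 (0.0342), phototransduction at -0.18 (0.0366) and cholinergic genes at -0.21 (0.0458). Each of these 11 lists had adjusted p = 0.619 with an estimated correlation. Of these 15 list calls 8 held without joint exposure replicate 3, 9 without nicotine replicate 2, 11 without joint exposure replicate 1 or 2 or nicotine replicate 1, and 12 without nicotine replicate 3. The metal, neuropeptide, odorant-binding, ribosome, apoptosis and digestive tract calls held whichever single array was left out. The digestive tract call was lost without joint exposure replicates 1 and 2 together (adjusted p = 0.328), a fit that leaves 1 joint array and takes its spread from the other groups. With the 3' minus middle covariate 12 of the 15 calls held, without head fat body (0.211), respiration (0.124) and lipid genes (0.201). Without control replicate 3 and joint exposure replicate 1 together 11 held, and the peptide (0.115), apoptosis (0.0580), head fat body (0.115) and lipid (0.0828) calls were lost. The 3' minus 5' covariate ended the cholinergic call (0.0509), and with no filter 14 of the 15 list calls held.

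The 2 paraquat contrasts have no array in common. Across 7316 genes their log2 changes correlated at r = 0.546 (Spearman rho 0.523), where genes are not independent replicates. Of 22 genes called higher without nicotine and 29 with it, 18 were shared, Cyp6d2, Ku80 and AOX1 among them, where independent calls would share 0.0872. Of 2 and 5 called lower, 2 were shared, where independent calls would share 0.00137, and 0 genes were called in opposite directions. CG33468, called without nicotine, was not called with it (adjusted p = 0.0649). All 24 genes called without nicotine had the same sign with it, and all 34 called with nicotine had the same sign without it.

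**Figure D3:**
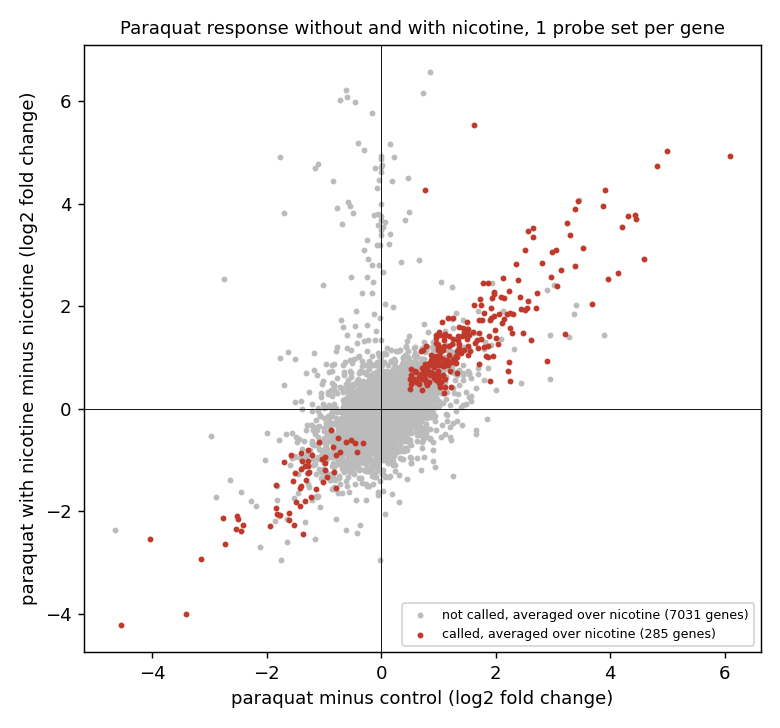
Log2 fold change with paraquat without nicotine (x axis) against that on nicotine (y axis), 1 probe set for each of 7316 genes, red where called in the averaged contrast (285 genes) and grey otherwise. The called genes lie on the same side of 0 on both axes, which their choice by the mean of both contrasts favours. Across all genes r was 0.546.

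Nicotine without paraquat was asked for its own effect. The smallest p-values belonged to Obp99b at -1.16 ± 0.22 log2, CG15449 at -1.46 ± 0.31, squ at -0.96 ± 0.22, Sb at 0.89 ± 0.21 and CG13305 at 2.41 ± 0.56 (n = 3 and 3). None passed the test (adjusted p = 1). The dopamine synthesis gene ple was at 0.30, Ddc at -0.03, Sod2 at 0.03, Cat at -0.03, GstD1 at -0.19 and Pink1 at -0.16 (adjusted p = 1). Limma called 0 probe sets, with 179 at an unadjusted p below 0.05, fewer than the 455 that chance would give, and 2 were called without nicotine replicate 2. Counts under chance also arose for nicotine with paraquat (275), nicotine averaged (336) and the interaction (112). The p-values of these contrasts thus ran large, for a cause not tested, and 0 calls are no evidence that nicotine had no effect. Among lists, cuticle genes were higher in 19 of 21 (median 0.27, camera adjusted p = 0.00272, and adjusted p = 0.850 with an estimated correlation). Antimicrobial peptide genes were higher in 12 of 15 (median 0.24, camera adjusted p = 0.00975) and lipid and glycogen genes lower in 17 of 17 (median -0.21, camera adjusted p = 0.00975). Muscle genes were lower (median -0.19, camera adjusted p = 0.0169). These 3 lists each had adjusted p = 0.876 with an estimated correlation. No list call held whichever array was left out. The cuticle call was lost without control replicate 3 (adjusted p = 0.0786) or nicotine replicate 3 (0.0557), and the peptide call without control replicate 2 (0.159) or nicotine replicate 3 (0.243). The lipid call was lost without control replicate 2 (0.0589) or 3 (0.142), and the muscle call without control replicate 1 (0.184) or 3 (0.193) or nicotine replicate 1 (0.207) or 2 (0.119). Without control replicate 3 and joint exposure replicate 1 together the cuticle (0.120), lipid (0.153) and muscle (0.166) calls were lost, and the lipid call also with the 3' minus middle (0.193) or 3' minus 5' covariate (0.573).

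With paraquat present, the same question was asked of flies on both compounds against paraquat alone. The smallest p-values belonged to the BMP receptor gene tkv (at least 1.59-fold lower), the metallothionein gene MtnC (at least 18.4-fold higher), CG12780 (at least 12.7-fold higher), CG10185 (at least 2.87-fold lower) and Fen1 at -1.43 ± 0.33 (n = 2 and 3). None passed the test (adjusted p = 0.962). Limma called 0 probe sets, with 275 at an unadjusted p below 0.05, and 32 were called without joint exposure replicate 3 and 1 without joint exposure replicate 1. Digestive tract genes had a median of 4.31 log2 (camera adjusted p = 3.11e-16, and adjusted p = 0.289 with an estimated correlation). The 26 proteasome genes were all lower (median -0.38, camera adjusted p = 7.38e-06, and adjusted p = 0.821 with an estimated correlation), a call lost with the 3' minus middle covariate (adjusted p = 0.0542) and without joint exposure replicates 1 and 2 together (0.161, with 1 joint array left). The subject genes were at 0.37 for ple, -0.38 for Cat, -0.29 for Sod2, -0.10 for GstD1 and -0.36 for Pink1.

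Averaged over paraquat, the smallest p-values for nicotine belonged to Obp99b at -0.87 ± 0.16 log2, the nuclear receptor gene Hr38 at 2.26 ± 0.45, Odc2 at 1.29 ± 0.29, CG10185 (at least 2.06-fold lower) and MtnC (at least 4.41-fold higher). None passed the test over all probe sets (adjusted p = 0.833). Limma called 0, with 336 at an unadjusted p below 0.05, 1 without joint exposure replicate 1, 2 without nicotine replicate 2 and 22 without joint exposure replicate 3. When adjusted over the list alone, MtnC was called higher among metal-handling genes and Obp99b lower among odorant-binding genes. The receptor genes nAChRalpha7 at -0.50, nAChRbeta3 at -0.30 and nAChRalpha2 at 0.26 were not called, and the cholinergic list had a median of 0.06 (camera adjusted p = 0.474). Not called either were ple at 0.33, Pink1 at -0.26, Cat at -0.20, Sod2 at -0.13, GstD1 at -0.14 and Ddc at -0.01. Called lists were digestive tract (median 2.06, camera adjusted p = 2.00e-08, and adjusted p = 0.591 with an estimated correlation) and proteasome (-0.21, 26 of 26 lower, camera adjusted p = 0.000976, and adjusted p = 0.910 with an estimated correlation). Cuticle genes were called as well (0.14, camera adjusted p = 0.00477, and adjusted p = 0.817 with an estimated correlation). The proteasome call was lost without paraquat replicate 3 (adjusted p = 0.123) and the cuticle call without paraquat replicate 3 (0.214) or joint exposure replicate 2 (0.0690). Both were lost without joint exposure replicates 1 and 2 together (0.177 each, with 1 joint array left). The proteasome call was also lost with the 3' minus middle covariate (0.434) and without control replicate 3 and joint exposure replicate 1 together (0.258). With no filter 2 of the 3 list calls held. The 2 nicotine contrasts correlated at r = 0.234 across 7316 genes (rho 0.300), which are not independent replicates.

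The joint exposure was compared with control for their combined effect. Cyp6d2 rose by 4.53 ± 0.45 log2 (23.2-fold, adjusted p = 0.00446) and CG31288 by 4.45 ± 0.38 (21.9-fold, adjusted p = 0.00248). CG12766 rose by 4.08 ± 0.60 (adjusted p = 0.0235), Ku80 by 3.95 ± 0.55 (15.4-fold, adjusted p = 0.0230) and CG12224 by 3.72 ± 0.47 (13.2-fold, adjusted p = 0.0176). GstE9 rose by 3.69 ± 0.55 (12.9-fold, adjusted p = 0.0235). Cyp313a1 fell by 2.47 ± 0.35 (5.53-fold, adjusted p = 0.0231), Obp56h by 1.58 ± 0.22 (2.98-fold, adjusted p = 0.0231) and CG13833 as well (adjusted p = 0.0176). Not called were ple at 0.03 (0.960), Ddc at -0.19 (0.675), Sod2 at -0.36 (0.481), Cat at 0.07 (0.876), GstD1 at 0.53 (0.293) and Pink1 at -0.54 (0.281). In all 30 probe sets were called, 27 higher and 3 lower, with 1501 at an unadjusted p below 0.05. The count was 5 without control replicate 2, 7 without control replicate 3, and 11 without control replicate 1 or joint exposure replicate 1. It was 14 without nicotine replicate 1, 66 without joint exposure replicate 3 and 381 without joint exposure replicate 2. Of the 9 named genes 2 kept their call without control replicate 2 or 3 or joint exposure replicate 1, and 4 without control replicate 1 or nicotine replicate 1. The number was 7 without paraquat replicate 2 or 3, and 8 without joint exposure replicate 3. With the 3' minus middle covariate, the 3' minus 5' covariate or only the groups compared 1 of the 9 kept its call. With no filter, or without control replicate 3 and joint exposure replicate 1 together, all 9 lost it.

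Lists called for the joint exposure were digestive tract (median 4.06, camera adjusted p = 4.19e-05), neuropeptides (-0.43, 5.37e-05), lipid and glycogen (-0.57, 0.000261) and metal handling (0.40, 0.000511). Of the lipid genes 0 were called by limma, and 1 higher and 8 lower when adjusted over the list alone. Further calls were apoptosis, DNA damage and JNK (0.40, 0.00166), cytosolic ribosome (-0.22, 0.00166), neuronal (-0.41, 0.00166) and head fat body genes (-0.58, 0.00233). Also called were phototransduction (-0.26, 0.00271) and odorant-binding genes (-0.29, 0.00838). These 10 lists each had adjusted p = 0.550 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.21 (camera adjusted p = 0.00298, and adjusted p = 0.622 with an estimated correlation). That call was lost without control replicate 3 (0.159) or joint exposure replicate 1 (0.110), and the phototransduction call without joint exposure replicate 3 (0.0670). The digestive tract call was lost without joint exposure replicates 1 and 2 together (0.304), with 1 joint array left. Of these 11 calls 7 held with the 3' minus middle covariate, without the head fat body (0.311), respiration (0.792), ribosome (0.311) and odorant-binding calls (0.257). Without control replicate 3 and joint exposure replicate 1 together 8 held, without respiration (0.809), ribosome (0.156) and odorant-binding genes (0.112). The respiration call was lost with the 3' minus 5' covariate too (0.0687).

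The interaction asked whether nicotine altered the response to paraquat. The smallest p-values belonged to tkv, CG31125 at -1.08 ± 0.28 log2, CG15629 at -1.89 ± 0.52, Utx at 0.84 ± 0.23 and Obp56f at -1.48 ± 0.41. None passed the test (adjusted p = 0.9997), and tkv has no size here because only its paraquat mean (4.67) lay above log2 4. For ple it was 0.07 ± 0.31, for Ddc 0.02 ± 0.30, for Sod2 -0.32 ± 0.36, for Cat -0.36 ± 0.27, for GstD1 0.09 ± 0.35 and for Pink1 -0.20 ± 0.34. Limma called 0 probe sets, with 112 at an unadjusted p below 0.05, and 1 without joint exposure replicate 1, 2 without nicotine replicate 2 and 21 without joint exposure replicate 3. Over the 336 probe sets that paraquat changed, the median interaction was -0.09 log2 (interquartile range -0.39 to 0.13) with a median 95% half-width of 1.04. For 90 of them the interval lay within 1 log2 of 0, and for the others it did not exclude a 2-fold difference.

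Some lists differed as a whole in the interaction. Digestive tract genes had a median of 4.53 log2 (camera adjusted p = 2.02e-13, and adjusted p = 0.451 with an estimated correlation). Antimicrobial peptide genes were lower in 13 of 15 (median -0.51, camera adjusted p = 0.00199), with Drs at -2.14 ± 0.73 and Mtk at -1.86 ± 1.07. Lower as well were proteasome genes in 24 of 26 (median -0.37, camera adjusted p = 0.00163) and odorant-binding genes in 26 of 30 (median -0.35, camera adjusted p = 0.00200). These 3 lists each had adjusted p = 0.891 with an estimated correlation. By limma 0 members of any list were called. The peptide call was lost without nicotine replicate 3 (adjusted p = 0.0951), and without control replicate 3 and joint exposure replicate 1 together (0.0770). The proteasome call was lost without paraquat replicate 3 (0.156), joint exposure replicate 1 (0.230), nicotine replicate 3 (0.0729) or joint exposure replicates 1 and 2 together (0.555, with 1 joint array left), and the odorant-binding call without paraquat replicate 2 (0.167), joint exposure replicate 1 (0.0722) or 3 (0.0846) or nicotine replicate 3 (0.0951).

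The digestive tract signal was largest on joint exposure replicates 1 and 2, and without that pair the list's interaction median was 1.29 log2 (adjusted p = 0.00645). That value rests on 1 joint array, whose spread was taken from the other groups. The mean over 16 digestive tract genes was 11.5, 9.80 and 7.02 log2 on joint exposure replicates 1, 2 and 3, against 3.97 to 6.95 on the arrays of the other groups. The maltase gene Mal-A1 stood at 15.05, 12.72 and 10.98 on these 3 arrays and the trypsin gene betaTry at 14.29, 13.94 and 10.41. Jon99Ci, Jon25Bi and Mal-A2 of this list passed the low-value filter only through joint exposure replicates 1 and 2. Averaged over nicotine, paraquat gave this list a median of 1.84 log2, 15 of 16 higher and 0 called by limma or adjusted over the list alone, with Mal-A1 at 2.05 (adjusted p = 0.160). That list had a camera adjusted p = 0.0270, and adjusted p = 0.568 with an estimated correlation, and the call was lost without control replicate 2 (0.103), paraquat replicate 2 (0.0546), joint exposure replicate 1 (0.156) or 2 (0.0641) or nicotine replicate 2 (0.140). It was also lost with no filter (0.106), without control replicate 3 and joint exposure replicate 1 together (0.179), and without joint exposure replicates 1 and 2 together (0.937). With values below log2 4 set to log2 4, the medians were 1.60 averaged over nicotine, 3.61 for paraquat on nicotine and 3.9999 for nicotine with paraquat. They were 1.98 for nicotine averaged, 3.72 for the joint exposure and 3.87 for the interaction.

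**Figure D4:**
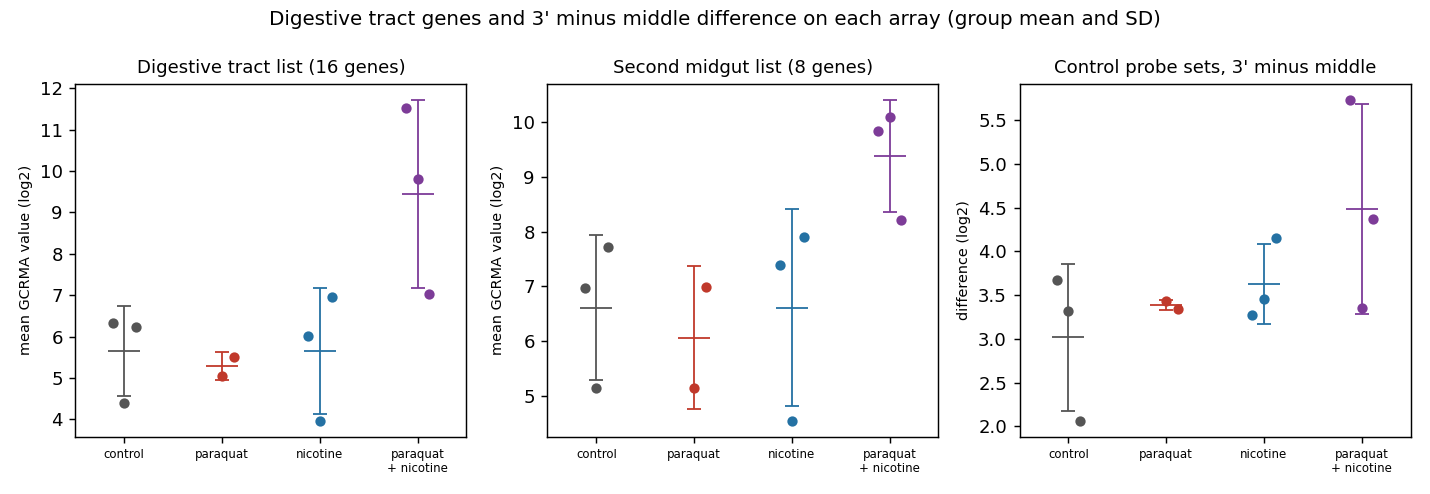
Mean log2 expression of 16 digestive tract genes and of 8 further midgut genes, and the 3' minus middle difference of control probe sets (log2), on each array with group mean and SD. Joint exposure replicates 1 and 2 lie at 11.5 and 9.80 for the digestive tract list, and joint exposure replicate 1 at 5.73 for the 3' minus middle difference.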

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

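Of the tests in this part, those of 3' bias and of a response shared by all joint pools, and the fit without joint exposure replicates 1 and 2, were chosen only after the result was seen.

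The response to paraquat differed with nicotine for 4 gene lists by the test of the interaction. The median interaction was 4.53 log2 for digestive tract genes, -0.51 for antimicrobial peptides, -0.37 for the proteasome and -0.35 for odorant-binding proteins. The preset correlation gave each of them an adjusted p below 0.05 and the estimated correlation did not (0.451 for the digestive tract, 0.891 for the others). Without joint exposure replicates 1 and 2, which leaves 1 joint array with its spread taken from the other groups, the digestive tract median was 1.29 (adjusted p = 0.00645) and the proteasome median -0.11 (adjusted p = 0.555). Without control replicate 3 and joint exposure replicate 1 the antimicrobial peptide call was lost (median -0.20, adjusted p = 0.0770). Without nicotine replicate 3 the antimicrobial peptide median was -0.30 (adjusted p = 0.0951), and the proteasome and odorant-binding calls were lost there too (0.0729 and 0.0951).

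Control probe sets for RNA quality, left out of the tests of genes and used only for covariates in other fits, showed a larger 3' minus middle difference than any control array on 3 arrays. The difference was 5.73 log2 on joint exposure replicate 1, 4.38 on joint exposure replicate 3 and 4.15 on nicotine replicate 3, against 2.06 to 3.67 on the control arrays. A larger difference is what more degraded RNA would give with amplification from the 3' end, and all 3 pools came from flies on nicotine. Joint exposure replicate 2 (3.35) and nicotine replicates 1 (3.28) and 2 (3.46) lay within the control range. The 3' minus 5' difference was 8.49 on joint exposure replicate 3 and 8.39 on nicotine replicate 3, against 6.16 to 7.91 on the control arrays. On joint exposure replicate 1 it was 7.88, within that range, so the measures disagree on that array.

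On joint exposure replicates 1 and 2, 15 and 13 of 16 digestive tract genes, Mal-A1 and betaTry among them, exceeded all 8 arrays of the other groups, against 2 of 16 on replicate 3. These 16 are the members of a list of 43 that passed the low-value filter. Jon99Ci, Jon25Bi and Mal-A2 passed it only through replicates 1 and 2, so their excess there was set by the filter. The tables argue against 3' bias as the whole cause, since the median interaction was 4.37 log2 with the 3' minus middle covariate and replicate 2 had a difference of 3.35, within the control range. A candidate explanation is midgut tissue carried into some head pools. A second list of 8 midgut genes, written before its values were read, had median excesses of 3.65 and 3.83 log2 over the mean of those 8 arrays, and 5 and 6 of its 8 genes exceeded every one of them. Its member mex1 likewise passed the filter only through replicates 1 and 2. A response of the head shared by all joint pools cannot be told apart from midgut tissue. By the mean of the digestive tract list, replicate 3 exceeded the highest other array by 0.0764 log2, against an SD of 1.02 among those 8 arrays. By the median over the 16 genes, its excess over the mean of the 8 was 1.34, below the 1.56 of nicotine replicate 3. By the second midgut list, the median excess of joint exposure replicate 3 was 1.85, above the 1.43 of control replicate 3, the highest of those 8 arrays. On it 2 of the 8 midgut genes exceeded all 8 arrays.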

How the results depend on the processing

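The fits with the 3' minus middle covariate, without control replicate 3 and joint exposure replicate 1 (the extreme pair), and without joint exposure replicates 1 and 2 (the digestive pair) were chosen after seeing the data. All 336 calls of averaged paraquat kept their direction with the 3' minus middle covariate at an unadjusted p below 0.05, and 205 of them were still called (215 without the extreme pair). For genes named by size, 1070 of the values under other settings kept direction and call, 393 kept direction and lost the call, and 0 reversed. In fits that leave out or weight arrays a reversal could not occur, because these genes were chosen for no overlap between the groups. Nor could it with other filters, the variance trend, 1 probe set per gene or only the groups compared, which keep the group means. Only centring, the block and the covariates could have reversed a gene.

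Counts of called probe sets moved as follows, and the cause was not tested. Paraquat without nicotine (31) gave 7 with no filter, 62 with a variance trend, 765 with array weights, 9 with the 3' minus 5' covariate, 13 with only its groups, 2 without the extreme pair and 147 without the digestive pair. Paraquat on nicotine (41) gave 9 with no filter, 312 with weights, 18 with the 3' minus middle covariate, 2 with only its groups, 26 without the extreme pair and 125 without the digestive pair. Averaged paraquat (336) gave 137 with no filter, 1627 with weights and 592 without the digestive pair. The joint exposure (30) gave 1 with no filter, 47 with the filter at log2 6, 72 with a trend, 48 with centring, 278 with weights, 3 with either covariate, 3 with only its groups, 3 without the extreme pair and 171 without the digestive pair.

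Counts of 0 moved too. Nicotine alone gave 20 with weights. Nicotine with paraquat gave 4 with no filter, 1 without the extreme pair and 2 without the digestive pair. Nicotine averaged and the interaction each gave 3 with no filter and 1 without the digestive pair. The weights ran from 0.231 for joint exposure replicate 1 to 5.82 for nicotine replicate 1.

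Where leaving out arrays left 1 for paraquat, or 1 for the joint exposure without the digestive pair, that array was assumed to vary like the other groups. Leaving out each array gave 0 to 103 for paraquat without nicotine, 12 to 242 on nicotine, 53 to 586 averaged, and 5 to 381 for the joint exposure. It gave 0 to 2 for nicotine alone, 0 to 32 with paraquat, 0 to 22 averaged and 0 to 21 for the interaction. The correlation of the paraquat responses across genes (0.546) ran from 0.364 without joint exposure replicate 3 to 0.618, and was 0.674 with weights and 0.762 without the digestive pair. That of nicotine (0.234) ran from 0.118 to 0.303, and was 0.361 with weights, 0.334 with the 3' minus 5' covariate and 0.390 without the digestive pair.

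The replicate number as a block is not a pairing given by the labels. With the block the counts were 9 for paraquat without nicotine, 32 on nicotine, 359 averaged, of which 284 were among the 336, and 18 for the joint exposure. The correlation was 0.631 for paraquat. Without nicotine 5 of the 15 named genes kept their call with the block, on nicotine 13 of 17, and the averaged glutathione S-transferase call was lost (adjusted p = 0.0793). By value, 9 of the 11 arrays correlated best with an array of their own number, which hints at a pairing but does not establish it.

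The oxidative phosphorylation median for the joint exposure (-0.21) reversed to 0.0177 with the 3' minus middle covariate and 0.0295 without the extreme pair. Of the 15 list calls for averaged paraquat, 10 held with that covariate and 10 without the extreme pair. Values near the table's minimum, 39.9% of all, limit what low transcripts can show.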

Other observations

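Of the tests in this part, those of midgut tissue behind the paraquat calls, of a smaller neural share and of 3' bias in the neural lists without joint arrays, and the 3' minus middle covariate, were chosen only after the result was seen.

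Paraquat raised both subunit genes of the DNA end-binding Ku complex, Ku80 by 3.91 log2 and Irbp by 2.25, together with the nucleotide synthesis gene RnrL by 4.11, in heads where most cells no longer divide. The same heads had lower Gpdh1 (-2.06), sug (-2.12), FASN2 (-1.05) and foxo (-0.65) and higher ImpL2 (1.02), while the superoxide and peroxide genes Sod2 (-0.23) and Cat (0.28) were not called.

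The 336 probe sets changed by paraquat averaged over nicotine were examined for technical sources. Chance is argued against for this count, since 1 of 100 splits of the arrays, the real one, gave as many, and the highest of the others gave 49. The splits test the count and not any single gene. Loss of RNA 5' ends is argued against as the whole cause, since 100% of the calls kept their direction at an unadjusted p below 0.05 with the 3' minus middle covariate and their median size went from 1.30 to 1.20 log2, although 205 of the 336 were still called at an adjusted p below 0.05. Of the 41 calls of paraquat on nicotine, 41 (100%) had the same direction at an unadjusted p below 0.05 in the contrast without nicotine. That contrast compares no joint array, which argues against midgut tissue in the joint pools as the whole cause of these 41 calls. It cannot decide for the 336, which are calls of another contrast. Genes varying between joint pools as the digestive tract genes did were also unlikely to be called, so the 41 could hardly hold them. Less feeding on food with paraquat may underlie part of the fall in metabolic genes, which stays open beside that 100%, because no array measured food intake.

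Other splits of the arrays were counted for 4 further comparisons. For paraquat on nicotine (41 called) and the joint exposure (30 called), 1 of 10 splits, the real one, gave as many, with 2 and 1 in the highest of the others. With 10 splits they are too few for a share under 0.05. For nicotine alone and averaged, with 0 called, every split gives as many (10 of 10 and 100 of 100, with 0 and 31 in the highest of the others), so the splits say nothing on nicotine.

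Neuropeptide and neuronal genes, 40 in all, had a median of -0.37 log2 with paraquat. Their list calls rest on the preset correlation. With the estimated correlation 0 of 15 list calls held averaged and 0 of 12 without nicotine. Loss of RNA 5' ends is argued against as the whole cause, because with the 3' minus middle covariate both list calls held averaged and without nicotine, where 97.2% of the median was kept, while 5 other list calls of the averaged contrast were lost. A part of it cannot be told apart from a change in these genes, because the averaged median kept 85.1%, short of the 90% set before that fit was run. A smaller neural share, which would raise markers of other head tissues, cannot be told apart either. Averaged, the head fat body median of -0.47 lost its call with the covariate (-0.30, adjusted p = 0.0535). Without nicotine, the head fat body median of -0.34 kept its call with that covariate but lost it with the 3' minus 5' covariate. Averaged, the haemocyte (0.10), muscle (-0.06) and cuticle (-0.11) lists were not called. Nor was the glial list (-0.17), which is itself of the nervous system. A lower transcript level in neurons, a loss of peptide-producing cells, and lower feeding may each contribute and were not tested.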
